A study of Homo sapiens with 17 samples.

How the data were processed

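Expression was measured by RNA sequencing in cells made from the human embryonic stem cell line H1. Per the labels, RNA was taken with Trizol and libraries were made with an Illumina TruSeq RNA kit from 1 µg of total RNA. Groups were taken from the sample titles. For the 4 sorted libraries the titles give a vitamin C condition and a replicate number each, whereas the descriptions give the same condition to both libraries of a number, so that titles and descriptions disagree for 2 of the 4. The titles were used and the descriptions tried as an alternative. Cells negative for the reporter, which the series design also mentions, were not analysed here.

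The authors deposited 1 table per library. The processing notes name HISAT2 2.0.4, SAMtools 1.3.1, HTSeq 0.6.0 and DESeq 1.18.1 and the builds hg38 and GRCh38, without saying what each did. The authors' 13 tables of the course and of the adherent and suspended cells hold raw counts of reads for 58302 gene identifiers. The 4 deposited tables of the sorted cells hold values that were read as TPM: they sum to 995020 to 996531 over 28285 identifiers with 2 decimals, and their ratio to the counts fell with exonic gene length (log2 slope -0.644 over 8641 genes). How these TPM values were made is not stated. They list no mitochondrial gene and 4 ribosomal protein genes, and no whole reads can be recovered from them, so the depth of the sorted libraries is unknown. The analysis had been planned for counts in all tables, and the planned fallback was used for the sorted cells. The planned runs of count tests, size factors and count filters on them were not done.

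Genes were named from the gene table and GENCODE release 29 (GRCh38). The strand of the libraries and the annotation used for counting are not stated, so counts of overlapping and antisense genes are uncertain, as are those of close paralogs such as HBG1 and HBG2. Some genes with high TPM had almost no counts, and a few of these had a high count in single libraries, which is given where such a gene is named. Genes linked to sex and some other genes that the rule for named genes would name are not reported here.

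The sorted cells were tested with limma 3.58.1 (trend fitted, R 4.3.3) on log2(TPM + 1), which understates the change of low genes, for genes with at least 1 TPM in at least 2 libraries. Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr). All tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The vitamin C effect over the course was fitted with the time point as a factor over 10 libraries. Changes with hours were fitted as 1 straight line per condition on the log scale, scaled to 60 h, and the difference in slope as the interaction. Since each condition and time has 1 library, p-values of the course measure departures among single libraries across times and say nothing about variation between cultures. CPM values of the course are TMM scaled. The SE of a log2 value was taken from the F statistic.

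Suspended and adherent cells have 1 library each, so no test was made. Their CPM are of the library total, log2 ratios had 0.5 CPM added, and intervals are exact Poisson intervals at 95%. A fold against a library with no count was computed against 3 counts per library. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

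The choices of groups, tests, alternatives, named genes and 30 gene lists were made before the data were examined. Lists covered cell types, transcription factors, signalling responses and vitamin C dependent enzymes, and 27 had at least 5 measured members. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves on balance one way without comparing it with other genes. With a preset correlation, 5 lists were called in the sorted cells, 13 for vitamin C over the course, 19 and 13 for hours with and without vitamin C, and 14 for the difference in slope, and with an estimated correlation 0, 2, 0, 2 and 2. For pairs of single libraries the list median was set against 10000 random lists matched on mean expression in 20 bins. Named genes were the 8 largest rises and 8 largest falls among called genes (mean of at least 5 CPM in the higher group, and over the course the same sign at all 5 times), 13 genes set in advance, and up to 4 members of each list with the smallest p. For single libraries they were the 8 largest ratios in each direction with at least 20 CPM in the higher library. Clone names and genes on the Y chromosome were passed over.

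The alternatives were DESeq2 size factors, DESeq2 1.42.0, no filter, leaving out each library, leaving out the 0 h pair, no term for time, time ranks, other pseudocounts, the descriptions' groups, a block by replicate number, the 0 h pair added to the sorted cells, and 5 CPM added to ratios. Quantile normalization of the sorted cells, TMM scaling of the single library ratios and time as a factor in the difference in slope were added after seeing the data. Replicate numbers were not used to pair the sorted libraries, since 2 pairs are too few to establish pairing (correlation of deviations 0.565). The SD, SE and list tests of the sorted cells therefore include the difference between the numbers, which was large. Between the numbers 239 genes were called in a fit that also held vitamin C. The tests were tried on simulated data made from the same libraries with known changes. For the course, counts were drawn independently around each gene's mean, with a spread set by its expression level. Apart from the known changes they held no change over time and no difference between cultures, so the rates apply to that simpler setting. The vitamin C test over the course found 85.9% of 2-fold and 98.0% of 4-fold changes, with 8 false calls among 16118 genes, and the slope tests with and without vitamin C found 10.3% and 4.08% of 2-fold and 65.0% and 51.0% of 4-fold changes over 60 h.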

Results

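RNA from endothelial cells and from the blood cells they give rise to in culture was sequenced in 17 libraries. The cells were made from H1, an established human embryonic stem cell line, and sorted for a green fluorescent reporter of GATA2, a transcription factor of blood stem cells and of the endothelium that forms them. The endothelial cells had been made without or with vitamin C, a cofactor of the dioxygenases that remove methyl groups from histones and DNA. In 4 libraries the sorted cells were read directly, with 2 libraries per condition. A further 10 libraries followed sorted cells after re-plating, at 0, 24, 36, 48 and 60 h without and with vitamin C, with 1 library for each combination. The last 3 libraries came from cultures with vitamin C: adherent cells at 60 h, suspended cells at 60 h and suspended cells at 96 h.

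The tables of the 4 sorted libraries held scaled values with no read depth, with 17214 to 17485 genes above 0 per library. The other 13 tables held read counts, from 6214675 in the 24 h library with vitamin C to 11058345 in the 96 h suspended cells. The course libraries lay between 6214675 and 8794604, and the 60 h libraries of adherent and suspended cells held 8117075 and 6957056. At these depths 1 read stood for 0.0904 to 0.161 CPM (counts-per-million, scaled to the library total), and 3 counts for 0.271 to 0.483 CPM. Mitochondrial genes took 4.15% to 6.08% of the counts over the course, 7.44% in the suspended cells at 60 h and 9.66% in those at 96 h. On the first principal component of these 13 libraries, with 61.9% of the variance, the suspended cells stood at 73.4 and 166 and every other library at or below -0.237. No label says whether libraries of a group came from separate cultures.

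The sorted cells address what vitamin C changed in the endothelium before blood formation. SOX17, an arterial endothelial transcription factor, stood at 248 ± 195 TPM (transcripts-per-million, SD, n = 2) with vitamin C and at 84.3 ± 58.2 without. HEY1, a Notch target of arteries, stood at 454 ± 279 against 197 ± 69.7 TPM, and MFNG, a glycosyltransferase that modifies Notch receptors, at 60.4 ± 35.9 against 18.8 ± 1.53 TPM. The proliferation gene MKI67 and the p53 regulator MDM2 were lower with vitamin C, at 67.6 ± 64.8 against 141 ± 21.2 TPM and at 38.7 ± 7.55 against 80.7 ± 20.8 TPM. None of these differences passed the test: limma called 0 of 14421 genes, and 313 had an unadjusted p under 0.05 where chance gives about 721. With the replicate number as a term limma also called 0, with 1237 at an unadjusted p under 0.05, more than the 721. GATA2 (log2 difference 0.27 ± 0.25, SE), RUNX1 (-0.22 ± 0.63), SPI1 (0.56 ± 1.03), MYB (-0.51 ± 0.47), GFI1 (-0.80 ± 1.31), SPN (-0.01 ± 0.47), CDH5 (0.33 ± 0.28), KDM6A (-0.14 ± 0.39), KDM6B (-0.21 ± 0.32) and EZH2 (-0.49 ± 0.31) were among the genes not called. Leaving out replicate 1 with vitamin C gave 1 gene. On simulated data of this size the test found 1.01% of 2-fold and 46% of 4-fold changes. The titles and the descriptions of these libraries disagree on vitamin C for 2 of the 4, and grouping by the descriptions called 156 genes, 37 higher and 119 lower.

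As groups, arterial endothelial genes were higher with vitamin C for 14 of 15 members, with a median log2 difference of 0.45 (adjusted p = 0.000613, but adjusted p = 0.939 with an estimated correlation). HEY1 (1.1 ± 0.51, SE), DLL4 (0.80 ± 0.50) and HEY2 (0.55 ± 0.26) were among them. Cell cycle genes were lower for all but 1 of 20 members (median -0.86, adjusted p = 0.000613, but adjusted p = 0.939 with an estimated correlation), with BUB1 at -1.41 ± 0.66 and AURKA at -1.27 ± 0.71. Genes of the p53 response (median -0.605, adjusted p = 0.00131) and the vitamin C dependent chromatin dioxygenases (median -0.33, adjusted p = 0.00853) were lower and Notch targets higher (median 0.11, adjusted p = 0.00998). These 3 lists also had an adjusted p = 0.939 with an estimated correlation. The mean level of the cell cycle list was 5.36 on the log2 scale in replicate 1 with vitamin C and 6.96, 7.24 and 7.22 in the other libraries, so 1 library carried most of the difference. The mean of the arterial list was 8.13 with and 6.90 without vitamin C in replicate 1, but 5.77 and 5.70 in replicate 2. Libraries of the same number stood together on the first principal component, which held 63.7% of the variance, and 239 genes were called between the numbers in a fit that also held vitamin C. RUNX1 was 39.6 and 34.9 TPM in the replicates numbered 1 against 108 and 89.9 TPM in those numbered 2. In all lists together 1 gene passed when adjusted over the list alone, an NF-kB target, the endothelial adhesion molecule SELE (-2.38 ± 0.43). Over the course SELE was called in the opposite direction (1.47 ± 0.28, adjusted p = 0.00872).

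**Figure D1:**
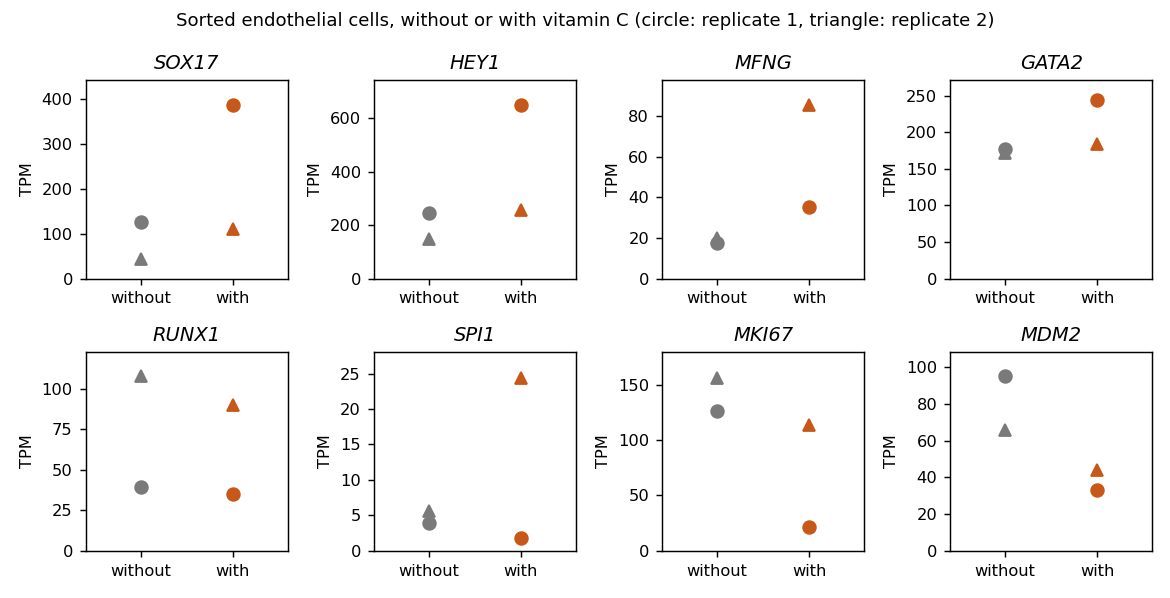
Levels in TPM (y axis, from 0) of 8 genes in the 4 sorted libraries, without and with vitamin C (x axis); each point is 1 library, circles replicate 1 and triangles replicate 2. SOX17 was 125 and 43.2 TPM without and 386 and 110 TPM with vitamin C, while SPI1 was 24.4 TPM in 1 library with vitamin C and at most 5.66 TPM in the other 3.

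The 0 h pair of the course was made from cells of the same description, so the vitamin C differences of both experiments could be set side by side. Over 12619 genes tested in both, Pearson's r across genes was 0.277 and Spearman's rho 0.261, and genes are not independent replicates. Within replicate number 1 the r was 0.189 and within number 2 it was 0.239. The 2 libraries on which titles and descriptions match gave 0.0264. Grouped by the descriptions, the sorted libraries gave an r of -0.142 and a rho of -0.106. Of 241 genes with an unadjusted p under 0.05 in the sorted cells, 191 had the same sign at 0 h. SOX17 was 232 CPM with and 105 CPM without vitamin C at 0 h, and HEY1 114 and 62.4 CPM. Of 858 genes called over the course and tested in the sorted cells, 69.5% had the same sign there, against 52% of the genes not called. The median log2 difference in the sorted cells was -0.348 for course calls lower with vitamin C but only 0.0552 for those higher. The haematopoietic transcription factor, leukocyte, megakaryocyte and myeloid lists had mean differences of -0.165, -0.168, -0.111 and -0.097 there and were not called. The blood gene rises of the course were thus not seen in the sorted cells, which were read before re-plating and cannot show what arose later. In the 0 h pair of the course the same lists had mean differences of -0.106, 0.3, 0.365 and 0.481. HOXA9, a homeobox gene far lower with vitamin C over the whole course, was 7.85 and 4.16 TPM without and 22.4 and 0.78 TPM with vitamin C in the sorted cells, so its sign differed between the replicate numbers.

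Taken over all times of the re-plating course, a set of blood cell genes was higher with vitamin C and several HOX and keratin genes lower. SPI1 (ENSG00000066336, chromosome 11, 47354860 to 47378576), the PU.1 transcription factor of myeloid cells, was higher by 3.25 ± 0.27 (log2, SE; adjusted p = 3.75e-05), at 6.01 to 33.4 CPM with against 0.349 to 3.78 CPM without. SPN, which encodes the leukocyte surface protein CD43, was higher by 2.44 ± 0.29 (adjusted p = 0.000399) and reached 49.0 CPM at 60 h against 7.56 CPM. HOXA9 (ENSG00000078399, chromosome 7, 27162435 to 27175180) had a difference of -3.74 ± 0.31 (adjusted p = 3.32e-05). It stood at 0.340 to 0.620 CPM with and 4.59 to 8.40 CPM without vitamin C. KRT8, a keratin of simple epithelia, was 237 to 259 CPM with and 576 to 660 CPM without vitamin C (-1.303 ± 0.06, adjusted p = 3.08e-07). In all, 955 of 16276 genes passed, 407 higher and 548 lower, of which 107 and 185 changed at least 2-fold.

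The largest differences with the same sign at all 5 times also included MFNG (2.40 ± 0.16), at 24.7 to 41.1 CPM with against 4.59 to 9.53 CPM without, and the orphan receptor GPR182 (3.804 ± 0.45). GPR182 stood at 19.4 CPM with vitamin C at 0 h, at 1.36 to 6.58 CPM later and at no more than 0.522 CPM without. CETP (2.33 ± 0.26), a lipid transfer protein, NAT8L (2.27 ± 0.27) and the adhesion molecule MADCAM1 (2.20 ± 0.27) were higher too. On the lower side stood the Wnt agonist RSPO2 (-4.40 ± 0.53), HOXA10 (-3.45 ± 0.38), HOXA11 (-3.33 ± 0.32) and PARM1 (-3.19 ± 0.38). They were joined by the muscle protein gene PDLIM3 (-2.95 ± 0.46), the growth factor HGF (-2.93 ± 0.34) and the protease PAPPA (-2.82 ± 0.36). HGF stood at 77.9 CPM without and 14.7 CPM with vitamin C at 0 h and at no more than 5.81 CPM in every later library. These genes passed at an adjusted p of 0.00285 or less, PDLIM3 having the largest.

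Among genes set in advance, MYB, a transcription factor of blood progenitors, was higher by 0.51 ± 0.09 (adjusted p = 0.00416) and SOX17 by 0.61 ± 0.10 (adjusted p = 0.00435). RUNX1, which drives the transition from endothelium to blood, was not called at 0.33 ± 0.10 (adjusted p = 0.0783), with 165 CPM with and 187 CPM without vitamin C at 0 h and 180 against 117 CPM at 60 h. GATA2 itself (0.02 ± 0.08), CDH5 (0.21 ± 0.08) and PECAM1 (-0.07 ± 0.07), markers of endothelium, and GFI1 (-0.45 ± 0.22) were not called either. The histone H3 lysine 27 demethylases KDM6A (-0.13 ± 0.11) and KDM6B (-0.13 ± 0.08) and the opposing methyltransferase EZH2 (0.23 ± 0.09) did not pass at adjusted p values of 0.589, 0.449 and 0.199. PTPRC did not pass the count filter.

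HOX genes formed the clearest group: 10 of 16 measured members were lower with vitamin C and none higher (median log2 difference -0.68, adjusted p = 8.04e-25, and adjusted p = 0.0188 with an estimated correlation). HOXB9, at 146 to 184 CPM with and 203 to 349 CPM without, was lower by a smaller margin (-0.73 ± 0.07) than the HOXA genes named above. Of the 16, 12 passed when adjusted over the list alone. Of 8 epithelial genes, 3 were lower, KRT8, KRT18 (-0.94 ± 0.06) and KRT19 (-1.61 ± 0.13), and none higher (adjusted p = 3.26e-13, and adjusted p = 0.0188 with an estimated correlation). EPCAM and CDH1 did not pass. These keratins are also made outside epithelia.

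Of 21 haematopoietic transcription factors 9 were higher and none lower (median 0.47, adjusted p = 3.78e-12, but adjusted p = 0.158 with an estimated correlation). They included LMO2 (0.75 ± 0.09), IKZF1 (1.21 ± 0.18) and TAL1 (0.51 ± 0.09). The mean difference of this list was -0.106 at 0 h and 0.653 to 0.884 at the later times, so it arose after re-plating. Of 17 leukocyte genes 7 were higher and none lower (median 0.74, adjusted p = 6.42e-10, but adjusted p = 0.168 with an estimated correlation), among them VAV1 (1.12 ± 0.13), PTPN6 (1.66 ± 0.20) and LCP1 (1.43 ± 0.21). Megakaryocyte genes were higher for 4 of 10 members, PLEK (3.02 ± 0.41), ITGA2B (1.84 ± 0.32), GP1BA (1.55 ± 0.28) and SELP (0.62 ± 0.16), and myeloid genes for 2 of 9. These were MRC1 (0.69 ± 0.09) and TYROBP, at 0 CPM in both libraries of 0 and 24 h and at 1.12, 2.42 and 4.06 CPM later with vitamin C against at most 0.261 CPM without. MRC1 was lower in suspended than in adherent cells at 60 h (26.3 against 205 CPM), unlike TYROBP (18.3 against 0.739 CPM). The megakaryocyte and myeloid lists passed with a preset correlation, at adjusted p = 1.14e-05 and 4.04e-05, and had an adjusted p = 0.0743 with an estimated correlation. None of 12 erythroid genes was called. When adjusted over the list alone, 10 transcription factors, 8 leukocyte, 4 megakaryocyte and 3 myeloid genes passed.

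Mesenchymal and smooth muscle genes were lower for 6 of 13 members and higher for none (median -0.72, adjusted p = 8.11e-11, but adjusted p = 0.105 with an estimated correlation), with TAGLN at -0.72 ± 0.10, COL1A1 at -0.73 ± 0.11, LUM at -1.39 ± 0.23 and COL3A1 at -1.14 ± 0.23. Genes of TGF-beta signalling and of the endothelial-to-mesenchymal transition were lower for 6 of 19 (adjusted p = 4.68e-08, but adjusted p = 0.103 with an estimated correlation), such as TGFBI (-0.90 ± 0.11). The p53 list was lower for 8 of 14 (adjusted p = 8.11e-11, but adjusted p = 0.138 with an estimated correlation). In it CDKN1A, the cell cycle inhibitor p21, was 60.6 to 198 CPM with and 150 to 400 CPM without vitamin C (-1.06 ± 0.11). PHLDA3 (-0.70 ± 0.09) and GDF15 (-0.96 ± 0.17) stood beside it. Genes of collagen modification went both ways, 3 higher and 6 lower of 21 (adjusted p = 0.00127, but adjusted p = 0.168 with an estimated correlation). The collagen cross-linking enzyme LOX was lower (-1.72 ± 0.12) and COL4A1 of basement membranes higher (0.38 ± 0.05). Of the mesenchymal, TGF-beta, p53 and collagen genes 8, 10, 12 and 10 passed when adjusted over the list alone.

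Interferon response genes were higher for 6 of 12 members and lower for 1 (median 1.19, adjusted p = 5.10e-08, but adjusted p = 0.0789 with an estimated correlation), such as ISG15 (1.14 ± 0.19) and OAS3 (1.6 ± 0.31). IFIT1 stood at 6.12 to 60.7 CPM with against 2.70 to 18.8 CPM without vitamin C (1.71 ± 0.20). Cell cycle genes were higher for 5 of 20, chiefly replication factors such as MCM3 (0.32 ± 0.06) and MCM6 (0.39 ± 0.08), and lower for none (adjusted p = 1.90e-06, but adjusted p = 0.492 with an estimated correlation). The mean difference of this list was 0.0423, 0.0215, 0.225 and 0.205 from 0 to 48 h and 0.77 at 60 h, so it came mostly from the 60 h pair. In sorted cells the list went the other way (-0.811), where 1 library carried most of the difference. Of 22 endothelial genes 6 were higher, such as ENG (0.62 ± 0.09) and PODXL (0.54 ± 0.09), and 1 lower (adjusted p = 0.00218, but adjusted p = 0.662 with an estimated correlation). Of 15 arterial genes 12 had a positive difference, with 4 called higher, JAG2 (0.53 ± 0.08), SOX17, IGFBP3 and NRP1, and 2 lower, JAG1 (-0.63 ± 0.10) and GJA5 (-0.39 ± 0.06). Their list was not called (adjusted p = 0.0614). The venous regulator NR2F2 was lower (-1.53 ± 0.26) and the cardiac regulator HAND1 also (-1.76 ± 0.15). The 19 vitamin C dependent chromatin dioxygenases were not called as a list (adjusted p = 0.472), with 1 member lower, KDM5B (-0.29 ± 0.08). In every list called, median, mean and test had the same sign. Adjusted over the list alone, 9 interferon, 7 cell cycle and 10 endothelial genes passed.

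With 1 library per condition and time, the spread behind these tests is how the difference varied over the 5 times, not variation between cultures. Leaving out either library of 24, 36 or 48 h also removes that time's difference: 611 and 610, 517 and 516, and 505 and 508 genes then passed (without and with vitamin C), and in each fit all 955 kept their sign.

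**Figure D2:**
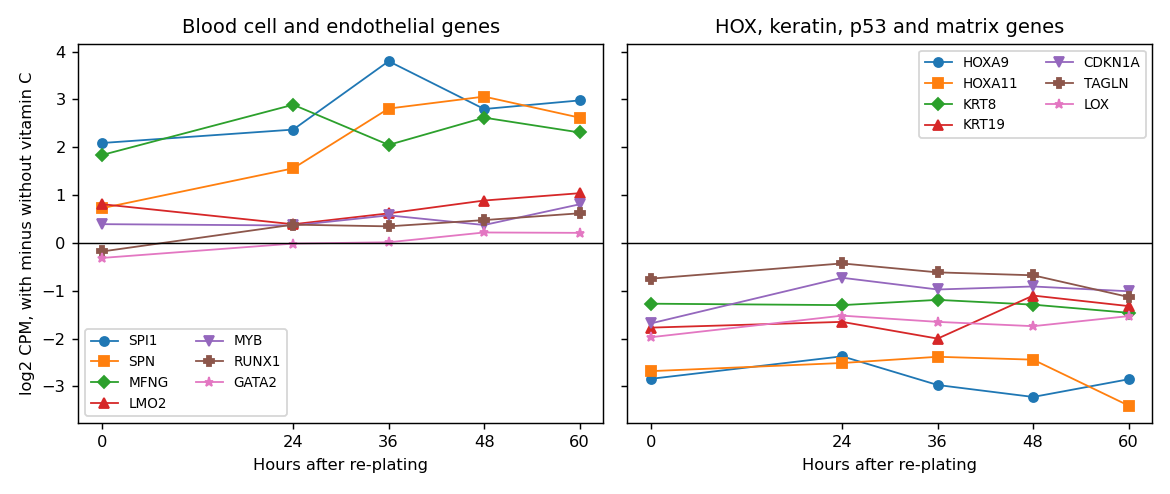
Difference in log2 CPM, with minus without vitamin C (y axis), at each time after re-plating in hours (x axis), with 1 pair of libraries per point and 1 line per gene. SPI1 stood at 2.09 at 0 h and 2.98 at 60 h, RUNX1 lay between -0.18 and 0.62, and HOXA9 between -3.22 and -2.37.

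The time course itself addresses what the sorted endothelium became after re-plating. With vitamin C, 289 of 16276 genes changed along the hours, 149 rising and 140 falling; slopes are given as log2 per 60 h. Haemoglobin genes rose from 0 counts: HBG2, a fetal haemoglobin, from 0 CPM at 0 h to 48.7 CPM at 60 h and HBD from 0 to 33.6 CPM. The platelet protein PLEK rose from 0.113 to 26.8 CPM (8.57 ± 0.91, adjusted p = 0.0044) and GATA1, the master regulator of red cells, from 0.227 to 26.3 CPM (6.49 ± 1.05, adjusted p = 0.0185). Of 10 megakaryocyte genes 2 rose, PLEK and ITGA2B (3.65 ± 0.63), and CLEC1B fell (-3.21 ± 0.29), with a list adjusted p = 0.0214, but adjusted p = 0.36 with an estimated correlation. MMP9, a matrix protease, rose from 10.99 to 726 CPM (6.13 ± 0.51, adjusted p = 0.00211), and TMEM100 (4.67 ± 0.66), MCTP1 (4.85 ± 0.50) and the Fc receptor FCGR2A (6.18 ± 1.28) rose too. SPN rose by 3.40 ± 0.67 (adjusted p = 0.037) and PECAM1 by 0.97 ± 0.20 (adjusted p = 0.0442). TRDN, a muscle gene, dropped from 32.9 CPM to 0 CPM in all 4 later libraries, and SOST, an inhibitor of Wnt signalling, from 235 to 7.25 CPM. COL26A1 fell from 58.0 to 1.02 CPM, XIRP1 from 42.7 to 0.870 CPM, CNTFR from 63.2 to 1.74 CPM, AKR1C3 from 49.7 to 1.31 CPM, FBN3 from 24.3 to 0.435 CPM and CRYBB1 from 19.6 to 1.02 CPM. These falls came mostly between 0 and 24 h: at 24 h COL26A1 was 5.36 CPM, CNTFR 4.22 CPM and AKR1C3 1.79 CPM.

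Arterial genes were the highest ranked of the 19 lists called with vitamin C (median slope 0.94, adjusted p = 3.31e-08, but adjusted p = 0.0517 with an estimated correlation), with MECOM (1.22 ± 0.22) and CXCR4 (3.37 ± 0.62) rising and SOX17 at -1.18 ± 0.28 not called (adjusted p = 0.0692). Of 12 erythroid genes 4 rose (adjusted p = 6.34e-08, but adjusted p = 0.26 with an estimated correlation), and of 17 leukocyte genes 3, WAS (2.21 ± 0.43), SPN and CORO1A (3.17 ± 0.65). The leukocyte list was called (adjusted p = 3.28e-05, but adjusted p = 0.271 with an estimated correlation). Of 21 haematopoietic transcription factors, GATA1 and NFE2 (4.05 ± 0.73) rose (list adjusted p = 0.0111, but adjusted p = 0.291 with an estimated correlation). GATA2 (0.97 ± 0.37), SPI1 (2.44 ± 0.71), RUNX1 (0.07 ± 0.20), MYB (-0.05 ± 0.37), GFI1 (-0.35 ± 0.49), CDH5 (0.13 ± 0.22), KDM6A (-0.03 ± 0.25), KDM6B (-0.07 ± 0.25) and EZH2 (-0.29 ± 0.27) were not called. Pluripotent cell genes such as LIN28A (-1.59 ± 0.29) and DPPA4 (-2.01 ± 0.35) and cardiac genes such as HAND1 (-3.92 ± 0.60) fell, for 2 of 6 and 3 of 11 members (adjusted p = 3.31e-08 and 3.07e-07, but adjusted p = 0.145 and 0.0621 with an estimated correlation). None of 20 cell cycle genes passed, although all 20 had a negative slope (list adjusted p = 3.71e-06, but adjusted p = 0.291 with an estimated correlation). The Notch target, hypoxia and interferon lists rose as groups (adjusted p = 0.00043, 2.46e-05 and 3.28e-05, and each an adjusted p = 0.0517 with an estimated correlation). No list kept its call with an estimated correlation. Adjusted over the list alone, 10 arterial, 8 erythroid, 5 leukocyte, 7 transcription factor, 6 pluripotent and 5 cardiac genes passed.

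The count of 289 leaned on single libraries. It was 9 without the 0 h library with vitamin C, 39, 45 and 127 without those of 60, 48 and 36 h, and 624, 183 and 112 without the libraries of 0, 36 and 48 h without vitamin C, which share the fit's spread. DESeq2 called 692, time ranks in place of hours 92, and the 24 to 60 h libraries alone 1814.

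Without vitamin C, 697 genes changed along the hours, 350 rising and 347 falling. MMP9 rose from 12.6 to 1439 CPM (6.71 ± 0.54, adjusted p = 0.000882). Lipoprotein lipase LPL rose from 15.2 to 676 CPM (5.69 ± 0.56), TMEM100 from 5.53 to 225 CPM (5.84 ± 0.68), FAM13C from 0.386 to 30.3 CPM and the lymphatic growth factor VEGFC from 0.514 to 24.3 CPM. CDKN1C and LSM14A were named for single libraries: at 60 h without vitamin C they stood at 23.9 and 49.95 CPM, and in every other course library at no more than 1.89 and 4.20 CPM. On the falling side, MYOCD, a muscle regulator, dropped from 24.9 to 0.130 CPM and SOST from 643 to 12 CPM (-5.96 ± 0.54, adjusted p = 0.00137). KLF4 dropped from 31.6 to 0.652 CPM, FBN3 from 29.5 to 0.782 CPM, SLC24A2 from 23.5 to 0.261 CPM, SSC4D from 24.7 to 0.391 CPM and MDGA1 from 36.4 to 0.782 CPM. TCF20 was 41.9 CPM at 0 h and at most 1.51 CPM in the other 9 course libraries.

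Arterial and Notch target genes rose most clearly without vitamin C. Venous and lymphatic endothelial genes did not rise with them, their mean being 5.04 log2 CPM at 0 h and 4.525 log2 CPM at 60 h. Of 15 arterial genes 10 rose and none fell (median slope 1.83, adjusted p = 1.52e-19, and adjusted p = 0.00237 with an estimated correlation). They included DLL4 from 116 to 939 CPM, HEY1 from 62.4 to 255 CPM, MECOM from 31.1 to 185 CPM and CXCR4 from 8.62 to 246 CPM. Of 11 Notch targets 6 rose and 1 fell (adjusted p = 2.58e-11, and adjusted p = 0.00445 with an estimated correlation). HES4 (3.44 ± 0.27), NRARP (3.19 ± 0.35) and DTX1 (5.09 ± 0.52) rose and HES1 (-2.53 ± 0.30) fell. Of 22 endothelial genes 6 rose (adjusted p = 1.19e-08, but adjusted p = 0.108 with an estimated correlation), among them PLVAP (2.53 ± 0.28), CLDN5 (4.18 ± 0.54) and PECAM1 (1.51 ± 0.20). Cell cycle genes fell for 9 of 20 members, such as MKI67 from 509 to 101 CPM and TOP2A from 557 to 91.0 CPM (adjusted p = 5.30e-14, but adjusted p = 0.178 with an estimated correlation). Cholesterol synthesis genes rose for 2 of 14, such as DHCR7 (1.37 ± 0.26), and as a list (adjusted p = 3.50e-07, but adjusted p = 0.123 with an estimated correlation). LIN28A (-2.03 ± 0.30), TBX5 (5.02 CPM at 0 h and at most 0.116 CPM later) and EPCAM (-3.93 ± 0.86) fell. So did the pluripotent, cardiac and epithelial lists (adjusted p = 1.16e-06, 1.54e-06 and 0.0212, but adjusted p = 0.172, 0.108 and 0.206 with an estimated correlation). TAL1 fell (-1.15 ± 0.22). RUNX1 (-0.68 ± 0.20), GFI1 (-1.73 ± 0.45), GATA2 (0.41 ± 0.37), SPI1 (2.08 ± 0.92), MYB (-0.39 ± 0.38), SPN (1.302 ± 0.69), CDH5 (0.76 ± 0.22), SOX17 (-0.45 ± 0.29), KDM6A (-0.73 ± 0.25), KDM6B (-0.34 ± 0.24) and EZH2 (-0.64 ± 0.26) were not called. Of 12 erythroid genes HBZ and HBA2 rose and 10 had a positive slope (median 1.65), and 6 passed when adjusted over the list alone, but the list was not called (adjusted p = 0.0559). None of 17 leukocyte genes passed, and their list was not called (adjusted p = 0.598). Of the arterial, Notch, endothelial, cell cycle and cholesterol genes 12, 8, 10, 12 and 9 passed when adjusted over the list alone.

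This count too leaned on single libraries: it was 141, 423, 302 and 257 without the libraries of 0, 36, 48 and 60 h without vitamin C and 382 without that of 48 h with vitamin C. DESeq2 called 1230 genes and the 24 to 60 h libraries alone 2545.

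Whether vitamin C changed the course itself was tested as the difference of both slopes. With 1 straight line per condition no single gene passed: edgeR called 0 of 16276, with 473 at an unadjusted p under 0.05 where chance gives about 814, and DESeq2 called 5. That fit leaves movement shared by both conditions, where it is off a line, in the spread. With the time point as a factor, a fit chosen after seeing the data, edgeR called 120 genes, 60 with a higher and 60 with a lower slope, and 1648 had an unadjusted p under 0.05. Higher slopes with vitamin C included PTGS1 (3.26 ± 0.24, adjusted p = 1.53e-05), MYC (2.30 ± 0.28, adjusted p = 0.00114) and NFE2 (2.88 ± 0.58, adjusted p = 0.0308). Lower ones included COL3A1 (-2.14 ± 0.18, adjusted p = 5.05e-05), EPAS1 (-1.54 ± 0.18, adjusted p = 0.00104) and DLL4 (-1.36 ± 0.17, adjusted p = 0.00142). The count of 120 was 54 and 53 without the 0 h libraries without and with vitamin C, and 37 without both. After 120 was seen, all 16 ways to assign the conditions within times were fitted in the same manner, and 1 of the other 15 called 200 genes.

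Both conditions shared part of the movement, with an r of 0.677 across genes between the slopes. Of 289 genes called with vitamin C, 284 had the same sign without, and of 697 called without, 677 had the same sign with vitamin C. The median ratio of slopes (with over without) was 0.654 over these 697 genes. They were picked for their slopes without vitamin C, which by itself lowers the ratio, so it cannot show that slopes were weaker with vitamin C. Called in both were 103 rises where independence gives 3.20 and 90 falls where it gives 2.98. As lists, Notch targets had a lower slope with vitamin C for 10 of 11 members (median difference -1.04, adjusted p = 6.24e-08, and adjusted p = 0.0254 with an estimated correlation), among them HES4 (-1.87 ± 0.36) and NRARP (-1.95 ± 0.46), and both of these passed with time as a factor. Arterial genes had a lower slope for 14 of 15 (median -0.75, adjusted p = 4.93e-09, and adjusted p = 0.0334 with an estimated correlation), with MECOM at -1.35 ± 0.32 and GJA4 at -1.55 ± 0.48. With time as a factor these lists had adjusted p = 1.37e-10 and 5.90e-14, but each an adjusted p = 0.0698 with an estimated correlation. The wider endothelial list was lower in that fit too, with 3 of 22 members positive (median -0.454, adjusted p = 4.08e-11, but adjusted p = 0.141 with an estimated correlation). Its mean difference was 0.524 at 0 h and -0.116 at 60 h. Lower slopes were thus not particular to Notch and arterial genes. The mean arterial difference, with minus without vitamin C, was 0.709 at 0 h and 0.103, 0.0401, -0.0112 and -0.109 at the later times, so this list rested mostly on the 0 h pair, and fry did not call it (adjusted p = 0.0673). The mean level of Notch targets was 5.24 log2 CPM with and 4.83 without vitamin C at 0 h, and 5.98 against 6.45 at 60 h.

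Some blood lists had a higher slope with vitamin C, while the myeloid and lymphoid lists were not called (adjusted p = 0.0562 and 0.612). All but 1 of 21 haematopoietic transcription factors had a higher slope (median 0.70, adjusted p = 3.00e-08, but adjusted p = 0.123 with an estimated correlation), with NFE2 at 3.19 ± 0.93 and RUNX1 at 0.75 ± 0.29. The same held for 15 of 17 leukocyte genes (median 0.82, adjusted p = 2.97e-08, but adjusted p = 0.168 with an estimated correlation), with CD33 at 1.95 ± 0.54 and RAC2 at 1.74 ± 0.53. The hypoxia list was also higher for 16 of 19 (adjusted p = 6.62e-06, but adjusted p = 0.0523 with an estimated correlation), with P4HA1 at 1.36 ± 0.25, and the cell cycle list for 20 of 20 (adjusted p = 2.00e-06, but adjusted p = 0.352 with an estimated correlation). The cell cycle list leaned on the 60 h pair, with a mean difference of 0.77 there and 0.205 at 48 h. The mean level of leukocyte genes went from 3.75 to 4.76 log2 CPM with vitamin C and from 3.43 to 3.33 without. The slope differences of GATA2 (0.55 ± 0.52), SPI1 (0.36 ± 1.27), MYB (0.34 ± 0.53), GFI1 (1.37 ± 0.68), SPN (2.10 ± 0.95), CDH5 (-0.63 ± 0.31), PECAM1 (-0.54 ± 0.28), SOX17 (-0.74 ± 0.40), KDM6A (0.70 ± 0.36), KDM6B (0.27 ± 0.34) and EZH2 (0.34 ± 0.38) all had an adjusted p of 1. With time as a factor none of the genes set in advance passed either, CDH5 having the lowest adjusted p (0.0573) and RUNX1 one of 0.108. Adjusted over the list alone, 2 Notch targets, 1 arterial and 1 hypoxia gene passed, with no gene of the transcription factor, leukocyte or cell cycle lists. With time as a factor it was 7 Notch targets, 9 arterial, 5 hypoxia, 9 transcription factor, 7 leukocyte and 8 cell cycle genes. On simulated data the straight line test of the slope difference found 3.03% of 2-fold and 21% of 4-fold changes over 60 h.

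**Figure D3:**
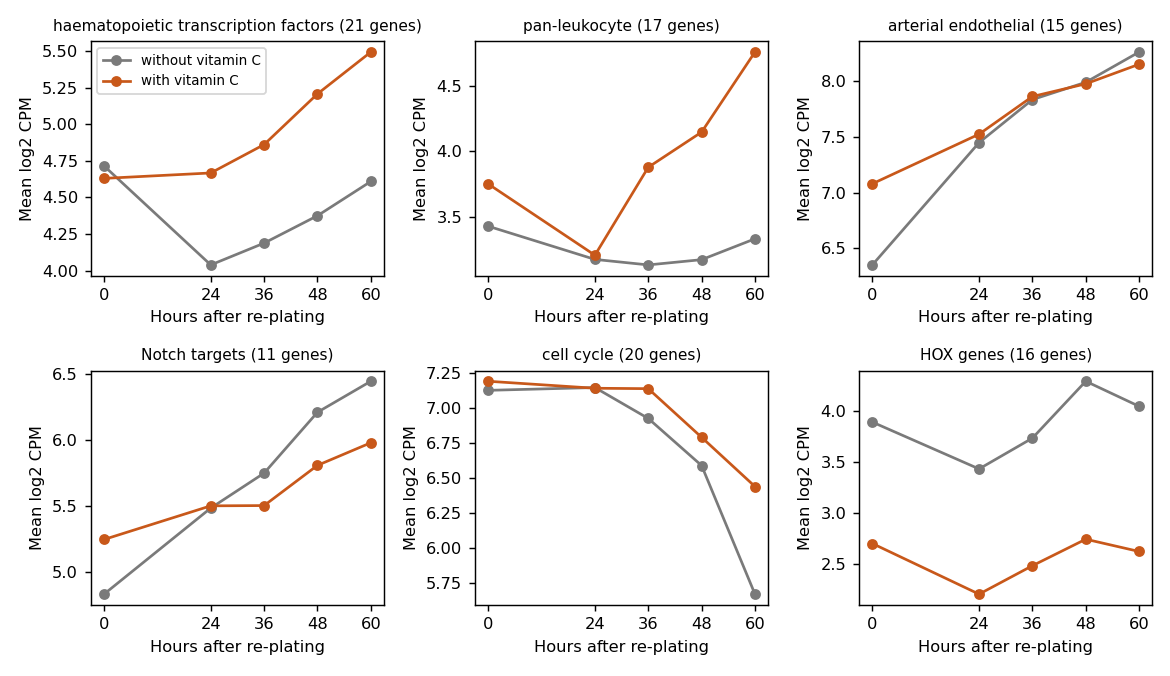
Mean log2 CPM of 6 gene lists (y axis, not starting at 0) against hours after re-plating (x axis), without (grey) and with vitamin C (orange), 1 library per point. Leukocyte genes reached 4.76 with against 3.33 without vitamin C at 60 h, while arterial genes went from 7.08 to 8.16 with and from 6.35 to 8.27 without.

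At 60 h the cultures with vitamin C held cells still attached and cells in suspension, which the labels call haematopoietic, and 1 library of each shows how they differed. Red cell genes were far higher in suspension: HBE1, an embryonic haemoglobin, stood at 225 against 2.46 CPM, HBZ at 74.7 against 0.493 CPM, HBG1 at 64.0 against 0.493 CPM and HBG2 at 307 against 4.07 CPM. CD84, a receptor of blood cells, was 70.1 against 0.246 CPM (95% Poisson interval 0.0298 to 0.890, from 2 counts), and SCGN, at 32.8 CPM, was at least 88.7-fold higher than 3 counts in the adherent library, which had none. Regulators of blood formation were higher as well, GATA2 at 965 against 172 CPM and RUNX1 at 502 against 111 CPM. GFI1 stood at 59.9 against 7.27 CPM, SPI1 at 144 against 12.3 CPM, MYB at 231 against 48.3 CPM and SPN at 264 against 8.13 CPM. The endothelial genes CDH5 (194 against 1350 CPM), PECAM1 (439 against 1150 CPM) and SOX17 (17.8 against 104 CPM) were lower. KDM6A (57.8 against 34.5 CPM), KDM6B (124 against 75 CPM) and EZH2 (95.6 against 49.2 CPM) differed by less than 2-fold.

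Of 9022 genes with at least 20 CPM in either library, 277 were at least 4-fold higher and 571 at least 4-fold lower in suspension. The largest falls in level were CBLN2 (0.719 against 29 CPM), the immediate early gene FOSB (7.76 against 158 CPM), the flow-induced factor KLF2 (3.31 against 57.4 CPM), MYORG (3.88 against 61.7 CPM), SEMA5B (1.87 against 30.3 CPM) and PLPP3 (16.1 against 208 CPM). TCF20, at 67.7 CPM against 2 counts (0.246 CPM), and RAB11FIP3, at 2.59 against 48.5 CPM, belong to the genes with a high count in single libraries. By list, erythroid genes had a median log2 ratio of 5.33, megakaryocyte genes 2.86, leukocyte genes 2.44, haematopoietic transcription factors 2.25, myeloid genes 2.14 and cell cycle genes 1.02. Each stood above all 10000 random lists of matched expression. Arterial genes had -2.89, endothelial genes -2.68 with all 22 members at least 2-fold lower, immediate early and heat shock genes -2.34, Notch targets -2.24, TGF-beta genes -1.90 and collagen genes -1.34, each below all 10000. TMM scaling shifted all log2 ratios of this pair by -0.12.

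By 96 h the suspended cells had gone further toward red cells and platelets. Haemoglobin genes took 1.05% of all counts, against 0.0913% in suspension at 60 h and 0.00118% in the adherent cells. HBG2 stood at 4720 against 307 CPM, HBE1 at 3490 against 225 CPM, the red cell membrane protein SLC4A1 at 167 against 1.15 CPM, and AHSP, a haemoglobin chaperone, at 58.5 against 0.144 CPM (0.00364 to 0.801, from 1 count). The platelet genes PPBP (171 against 0.719 CPM) and CLEC1B (45.8 CPM, also against 1 count) and the clotting factor F13A1 (39.4 CPM, at least 91.4-fold above 3 counts) were higher. BIN2 (169 against 1.58 CPM), SRGN (79.9 against 0.575 CPM) and the red cell enzyme PKLR (22.6 CPM, at least 52.4-fold above 3 counts) were higher too. Of 22 endothelial genes 17 were at least 2-fold lower and 1 higher. LPL was 137 CPM at 60 h and had no count at 96 h, at least 505-fold lower, and ADGRL4 was at least 175-fold and GASK1B at least 117-fold lower. CLEC14A (39.5 CPM at 60 h), FCN3 (82.1 CPM), TM4SF18 (48.9 CPM), TCF20 (67.7 CPM) and SOX17 (17.8 CPM) had 1 count each at 96 h (0.0904 CPM, 0.00229 to 0.504). HAPLN1 was 96.1-fold lower and CDH5 stood at 4.25 against 194 CPM.

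Early regulators stood lower at 96 h than at 60 h, with GATA2 at 309 against 965 CPM, RUNX1 at 289 against 502 CPM, MYB at 122 against 231 CPM and GFI1 at 20.2 against 59.9 CPM. SPN was 495 against 264 CPM, SPI1 105 against 144 CPM and PECAM1 559 against 439 CPM. KDM6A was 42.1 against 57.8 CPM, KDM6B 87.4 against 124 CPM and EZH2 94.0 against 95.6 CPM. Of 8509 genes with at least 20 CPM in either library, 128 were at least 4-fold higher and 208 lower. The median log2 ratio was 3.24 for erythroid, 2.93 for megakaryocyte, 1.75 for myeloid and 0.45 for leukocyte genes, each above all 10000 random lists. It was -0.36 for haematopoietic transcription factors, at percentile 1.58. It was -3.06 for endothelial and -3.32 for arterial genes, each below all 10000. Interferon response genes, lower in suspended than adherent cells at 60 h (median -1.28), were higher at 96 h (median 1.73), with MX1 at 36.5 against 1.01 CPM and IFI6 at 54.7 against 3.02 CPM. TMM scaling shifted all log2 ratios of this pair by 0.21 and turned 128 higher and 208 lower genes into 156 and 174.

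**Figure D4:**
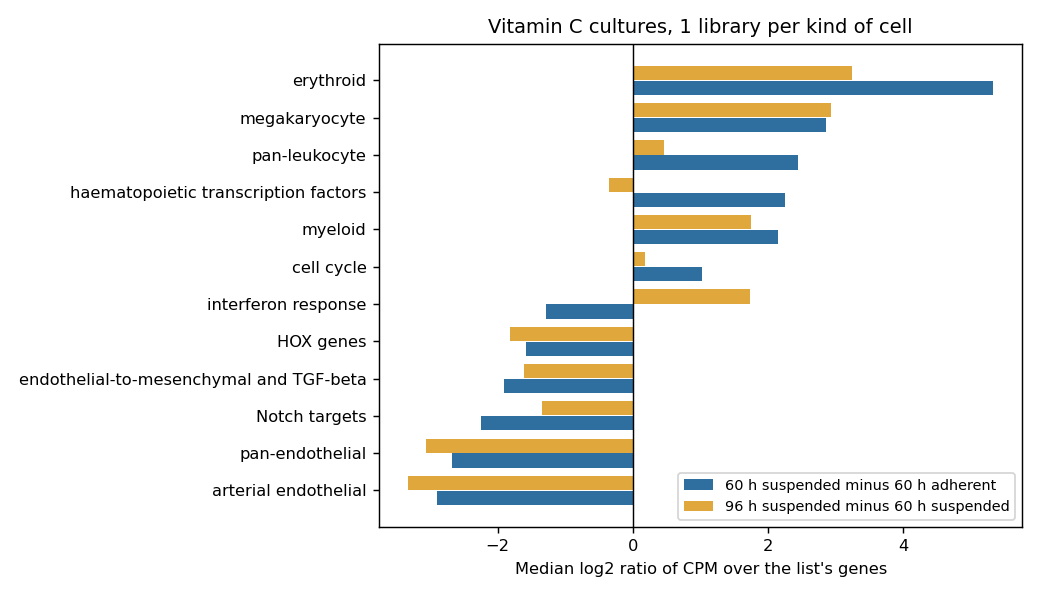
Median log2 ratio of CPM (x axis) over the genes of 12 lists (y axis), for suspended against adherent cells at 60 h (blue) and for suspended cells at 96 h against 60 h (yellow), with 1 library per kind of cell and no error. Erythroid genes stood at 5.33 and 3.24, arterial genes at -2.89 and -3.32, and interferon genes at -1.28 and 1.73.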

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

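The test of a lower share of endothelial cells and the fits of all 16 splits within times were chosen only after the result was seen. GCLC, the catalytic subunit of the enzyme that starts glutathione synthesis, was called in neither experiment and is given because its direction differed between them in every pair. Among genes called over the course, 212 had both sorted libraries of each condition apart in the same direction and 44 in the opposite direction. In sorted cells it was lower with vitamin C in both libraries (21.46 and 14.64 TPM) than in both without (27.66 and 26.76 TPM), a log2 difference of -0.5897 that was not called. Over the course it was higher with vitamin C at all 5 times (0.3065, adjusted p = 0.146), with 46.34 against 25.98 CPM at 0 h. The difference between the experiments was not tested, and no biological explanation was tested.

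In sorted cells the arterial genes SOX17 and HEY1 were higher with vitamin C and the proliferation gene MKI67 lower, under groups read from the titles. If the descriptions held instead, the sign of SOX17 would turn (-1.66 in place of 1.47). The descriptions' groups gave a correlation of -0.142 across genes with the 0 h pair, against 0.277 for the titles, and leaving out each of 23 chromosomes in turn gave -0.148 to -0.137 and 0.272 to 0.286. This argues against the descriptions as the true groups, but the reference is 1 unreplicated 0 h pair. Leaving out chromosomes reuses the same libraries and does not measure variation between libraries. The descriptions' groups are also the replicate numbers, so their correlation includes any difference between the numbers. The 2 libraries on which titles and descriptions match gave 0.0264. What stays open is a single wrong label, since each of the 4 libraries has 1 partner at most, and a difference between replicate numbers that is larger than that between conditions, with 239 genes called between the numbers in a fit that held vitamin C. In the fit of the same form for vitamin C, with the number as a term, limma called 0 (1237 at an unadjusted p under 0.05), and without it also 0 (313).

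Over the course, vitamin C cultures had more SPI1, SPN and MFNG and less HOXA9, KRT8 and CDKN1A. Of 126 ways to split the 10 libraries into 5 and 5, 100 were drawn, and 1 of these, the real split, gave as many as 955 genes, with 64 in the highest other. Most of these splits ignore the pairing by time. All 16 splits that part both libraries of every time, the real one included, are too few for a share under 0.05, and the highest other of these gave 19. A lower share of endothelial cells without vitamin C was predicted to raise the genes of every other cell type there. Leukocyte genes went the other way, with a median log2 difference of 0.736, 7 members higher with vitamin C and none lower. This covers leukocytes only, since only cell types present in a culture could rise. Mesenchymal and smooth muscle genes were lower with vitamin C at all 5 times, with a mean log2 difference of -0.533 at 0 h and -1.22 at 60 h. A candidate explanation for the blood genes is that more detached blood cells formed after re-plating: genes at least 8 times higher in suspended than adherent cells had a median log2 difference of -0.324 at 0 h and 1.44 at 60 h. A change within the endothelium stays open for SPI1, already 6.01 against 1.03 CPM at 0 h, and for HOXA9 and KRT8, lower at all 5 times, as does a difference between the parent cultures, since each time and condition has 1 library. For HOXA9 and KRT8 a larger share of other cells without vitamin C, such as mesenchymal cells, stays open too. In sorted cells KRT8 was 389 TPM with and 423 TPM without vitamin C, a log2 difference of -0.12 ± 0.23 (SE), and 12 of 19 HOX genes were higher with vitamin C, with a median of 0.10.

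For the difference in slope the real count was 0, so all 100 splits had to give at least as many and this test says nothing about chance. The highest other split gave 3100, but it kept both libraries of some times in 1 group, so its groups held different times. Each of the 9 drawn splits that part all 5 pairs of a time point, the real one included, gave 0. With time as a factor, a fit added after seeing the data, the real count was 120, and 2 of the 16 splits within times, the real one included, gave as many, with 200 in the highest other. A change of single genes in slope therefore stays open.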

How the results depend on the processing

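Quantile normalization of the sorted cells, TMM scaling of single library ratios and time as a factor in the difference in slope were chosen after seeing the data. Genes called and named for vitamin C over the course kept their direction in all 552 alternative values recorded. These values belonged to 79 genes, with 465 past the threshold and 87 not, and 10 genes passed in every recorded value. For fits leaving out a library, only the lowest and highest log2 value of each gene was recorded, so not every fit is covered. The genes with the largest differences had been picked for the same sign at all 5 times, which favours a kept direction. Called genes with hours kept their sign too, in 317 values with vitamin C (111 no longer past the threshold) and 439 without (93). In all, 241 named gene results had 1706 alternative values, of which 1350 were on the same side with the same sign, 291 lost the call, 18 gained it and 47 changed sign, the last for genes not called.

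In sorted cells 0 genes were called by limma (313 at an unadjusted p under 0.05) with pseudocounts of 0.1 and 5, no filter, the 0 h pair added, quantile normalization and a block by replicate number (1237 at an unadjusted p under 0.05, where chance gives about 721). The descriptions' groups called 156, and leaving out 1 library gave 0 to 1. Over the course the 955 genes were 951 with DESeq2 size factors, 853 with DESeq2, 1167 without the 0 h pair, 1591 without a filter and 28 with no term for time, which leaves the change over hours in the spread. Leaving out 1 library gave 505 to 1209, the lone library of that time then carrying no difference.

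For hours with vitamin C, the 289 genes were 289 with size factors, 692 with DESeq2, 438 without a filter, 1814 without the 0 h pair and 92 with time ranks. Leaving out 1 library gave 9 (0 h with vitamin C) to 624 (0 h without). For hours without vitamin C, the 697 genes were 693, 1230, 839, 2545 and 489 in the same order, and 141 to 1025 with 1 library left out. For the difference in slope edgeR called 0 (473 at an unadjusted p under 0.05), DESeq2 5, and the libraries from 24 h on 1. With time as a factor it was 120 genes (1648 at an unadjusted p under 0.05), 37 from 24 h on, and 53 (without the 0 h library with vitamin C) to 163 (without that of 24 h without vitamin C) with 1 library left out, 54 without the 0 h library without vitamin C. A factor takes up what both conditions share at each time, which lines leave in the spread. The cause was not tested for the counts that moved, apart from those named.

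Of gene lists, 5 were called in sorted cells with a preset correlation, 0 with an estimated correlation and 0 by fry. For vitamin C over the course 13 became 2 and 10, for hours with vitamin C 19 became 0 and 7, for hours without it 13 became 2 and 12, and for the difference in slope 14 became 2 and 1. With time as a factor the last were 15, 0 with an estimated correlation and 5 by fry. The correlation of sorted cells with the 0 h pair was 0.337 for genes with a mean of at least 10 in both. The 848 genes at least 4-fold apart between suspended and adherent cells were 594 with 5 CPM added and 879 with TMM, and the 336 between 96 and 60 h were 239 and 330.

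Among named genes, signs changed only in those not called. Of all 697 genes called for hours without vitamin C, 642 of 645 tested kept their sign without the 0 h pair and 655 of 658 without the 0 h library without vitamin C. With the descriptions' groups GATA2 was -0.22, RUNX1 1.38, GFI1 2.98, MYB 0.92, SPN 0.23, CDH5 -0.29, SOX17 -1.66, KDM6A 0.0925 and EZH2 0.36. SPN in sorted cells was 0.0044 with a pseudocount of 5, 0.21 with the 0 h pair added and 0.12 with quantile normalization, and KDM6A 0.0042 with the last. Leaving out 1 sorted library gave RUNX1 -0.93 to 0.49, GFI1 -2.42 to 0.82, SPI1 -1.02 to 2.14, MYB -1.09 to 0.065, SPN -0.40 to 0.37 and KDM6A -0.50 to 0.23. Leaving out 1 course library gave GATA2 -0.028 to 0.11.

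For hours with vitamin C and without the 0 h pair, GFI1 was 0.23, MYB 1.19, CDH5 -0.26, KDM6A 0.48 and KDM6B 0.10. With time ranks MYB was 0.0688 and KDM6A 0.0224. Leaving out 1 library gave RUNX1 -0.11 to 0.30, GFI1 -0.76 to 0.23, MYB -0.73 to 1.178, CDH5 -0.26 to 0.38, KDM6A -0.26 to 0.48 and KDM6B -0.14 to 0.097. For hours without vitamin C, MYB was 0.59 and KDM6B 0.13 without the 0 h pair, and with 1 library left out MYB was -0.79 to 0.59, KDM6B -0.71 to 0.13 and SPN -0.086 to 3.74. For the difference in slope, SPI1 was -1.03 and KDM6B -0.0267 without the 0 h pair. With 1 library left out GATA2 was -0.66 to 1.66, SPI1 -2.32 to 2.01, MYB -0.65 to 1.57, SPN -0.32 to 3.49, SOX17 -1.17 to 0.10, KDM6B -0.20 to 0.64 and EZH2 -0.20 to 0.60. The cause was not tested.

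Depth limits the low genes: 3 counts were 0.271 to 0.483 CPM, so genes such as HOXA9 with vitamin C (0.340 to 0.620 CPM) rested on few reads per library. For the sorted cells the depth is unknown, and the planned count tests, size factors and count filter were not run on them.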

Other observations

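Both tests of the missing genes were chosen only after the result was seen. Genes of detached blood cells stood higher in the course library with vitamin C at 60 h than at 0 h. The 132 genes at least 8 times higher in suspended than in adherent cells at 60 h, with at least 20 CPM, had a mean level of 1.99 log2 CPM at 0 h, 1.68 at 24 h and 3.92 at 60 h with vitamin C, and of 2.35, 1.17 and 2.20 without. For 128 of them tested over the course, the median log2 difference went from -0.324 at 0 h through 0.506, 0.698 and 0.967 to 1.44 at 60 h, with 28.9% higher with vitamin C at 0 h and 97.7% at 60 h. Of these, 31 were called higher and none lower. The 108 genes higher in adherent cells by the same rule had median differences of 0.43 at 0 h and -0.112 at 60 h.

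The 60 h course library with vitamin C was read as a mixture of cells like those of the adherent and suspended libraries. It then had a median of 15.3% of suspended cell RNA over the 132 genes (quartiles 13.5% and 17.4%) and 19.7% over the 108 adherent genes (12.9% and 27.8%). No label says that these libraries came from 1 culture. Both gene sets were picked from the adherent and suspended libraries themselves. The 60 h culture without vitamin C had 1.48% (-0.559% and 4%) over the suspended genes, and 14.5% (-10.4% and 35.4%) over the adherent genes, measured with the parts of the culture with vitamin C. Haemoglobin genes took 0.0149% of the counts at 60 h with and 0.00565% without vitamin C.

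For vitamin C over the course, the lists not described so far held few calls, and their results with hours are not given in full. For the difference in slope with time as a factor, camera called some of them. The antioxidant list was lower with vitamin C (adjusted p = 3.39e-06, but adjusted p = 0.0698 with an estimated correlation). The Polycomb list was higher (adjusted p = 0.00455, but adjusted p = 0.398 with an estimated correlation). Over the course, the lymphatic marker LYVE1 was higher with vitamin C (1.94) and APLNR of veins too (0.75). The venous and lymphatic list as a whole went the other way, with a mean difference of -0.577 to -0.0884 over the 5 times, and NR2F2 was lower. The inflammatory gene CCL2 was lower (-1.53) and SELE higher (1.47, adjusted p = 0.00872). In sorted cells SELE had the opposite sign (-2.38 ± 0.43, SE). The Polycomb repressive complex 2 genes held no call for vitamin C over the course (adjusted p = 0.472), nor did the antioxidant genes (adjusted p = 0.663). In suspended against adherent cells at 60 h, Polycomb genes had a median log2 ratio of 0.473 (percentile 92.1) and HOX genes of -1.58, below all but 0.01% of random lists.

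Some genes with high TPM in all 4 sorted libraries had almost no counts in the course: the tubulin gene TUBB averaged 2376 TPM and the channel gene CLIC1 1537 TPM, with 0 CPM at 0 h in both conditions. NOTCH4, an endothelial Notch receptor, averaged 124 TPM and stood at 0 and 0.115 CPM. Of 6069 expressed genes, 147 were missing in this way. In the major histocompatibility region of chromosome 6 it was 58 of 64 genes (90.6%), against 89 of 6005 elsewhere (1.48%; Fisher's exact test, two-sided, p = 3.58e-92). Genes taken as expressed had at least 20 TPM in all 4 sorted libraries, so this choice itself left out low genes. Within that set the missing genes did not stand at the low end, with a median of 67.6 TPM. The 25th percentile of the counted ones was 42.7 TPM. The region is held in several copies by builds with alternative sequences, so reads with more than 1 mapping place may have been left out of the counts, as may be so for EEF1G (3177 TPM) and MIF (730 TPM) elsewhere. For such genes a low count is no sign of low expression, and no biological explanation was tested.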
